A study of Mus musculus with 8 samples.

How the data were processed

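The series holds 8 mouse libraries of genomic DNA from splenic germinal center B cells of C57BL/6 animals that were wild type (WT) or knockout (KO) for TET2. In 4 of them DNA carrying 5-hydroxymethylcytosine (5hmC) had been immunoprecipitated before sequencing (hMeDIP-seq), 2 per genotype, numbered 2 and 3 in the labels of both genotypes. The other 4 are the input libraries, for which no processed values were analysed here. The labels do not say whether libraries of a genotype came from separate animals. The p-values of comparisons between libraries therefore measure only the spread between these libraries, which may be technical. Those from random gene lists measure the spread between genes in the authors' fixed set of regions. They and the binomial p for Vav1 measure no spread between libraries, so they do not show that a pattern would recur in other libraries.

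Per the submitters' processing notes, BWA 0.7.12-r1039 and MACS2 2.1.0.20151222 were used with the mouse genome build GRCm38.p3, and the notes give no settings. The authors deposited 1 peak list for each immunoprecipitated library, so peaks had been called per library and not on pooled libraries. Each deposited list gives a position, a summit, a fold enrichment (a ratio over the local background of the caller), a −log10 p-value and a −log10 q-value for every peak, in the column layout MACS2 writes. The deposited score of a peak was checked and equals the whole part of 10 times its −log10 q in at least 99.9997% of peaks. The lowest −log10 q in a list lay between 2.01 and 2.20. These per-peak values are the authors' own and were used to describe, rank or filter peaks within a list.

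The authors also deposited a pair of tables of differential regions. Per the file headers, 1 lists regions enriched in KO germinal center B cells and the other regions enriched in WT cells, which are called KO-higher and WT-higher here. Each region carries a deposited score, of at least 3.08. The scale of the score, the caller and the compared libraries are not stated in the sources used here. The names of the deposited tables carry tags that may mark a cutoff and replicates, but their meaning is not explained. The WT-higher and KO-higher calls are therefore the authors' comparison with no replicate values behind them.

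The number of reads per library is not given in the sources used here. Peak depth was recovered from the deposited fold enrichment and −log10 p of each peak, which together fix a whole pileup and a local background under the Poisson test of MACS2. Whole pileups were recovered for at least 99.9974% of peaks in every library, within 0.001 of the deposited −log10 p. The most frequent local background, taken as the depth of the library, was 11.6 reads in KO replicate 2, 10.9 in KO replicate 3, 8.66 in WT replicate 2 and 11.7 in WT replicate 3. It is not stated whether that background was computed from the input or from the immunoprecipitated library.

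Peaks of the 4 lists were merged where they touched or overlapped, which gave the union regions. A library had a region when at least 1 bp of its peaks lay in it. Pairs of libraries were compared by the Jaccard index of covered bases with bedtools 2.31.1. Values per library were compared between genotypes with an exact two-sided permutation test of the difference of means, which for 2 libraries against 2 cannot give a p below 0.333. Peaks specific to a genotype were counted beside the counts from the other splits of the 4 libraries, 3 splits in all.

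Gene positions came from a RefSeq table of GRCm38.p6, whose primary chromosomes have the coordinates of GRCm38.p3. The table has 1 span per gene, with neither strand nor exons, so exons, introns and promoters were not told apart. The planned window of the gene body plus 2 kb upstream was replaced by the span plus 2 kb on both sides, and the planned promoter class by positions within 2 kb of either gene end. Region midpoints were classed as gene end, inside a gene or outside genes. Shares in the differential tables were set against union regions with 95% intervals from 1000 bootstrap draws of 10 Mb blocks. CpG content, which needs the genome sequence, was not analysed here.

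For 21887 protein-coding genes, bases covered by peaks were scaled to equal totals and tested as log2(covered bases + 200) with limma 3.58.1 (trend and robust) in R 4.3.3, for genes with a mean of at least 500 covered bases. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes on this scale understate the change of genes with few covered bases. On simulated values for 14001 genes in that comparison, with 200 genes changed, 61.0% of 2-fold, 88.5% of 4-fold and 99.5% of 8-fold changes were recovered, with 9, 12 and 24 false calls. These values were drawn independently for each gene and library from the fitted variances. Shifts shared by many genes of a library were left out, so these shares do not give the power in the real data. Fixed gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01. The replicate number was not used as a block.

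The number of WT-higher regions per 10 kb of union peak coverage was compared, for each list, with 10000 random lists of the same size drawn within 20 bins of union peak coverage (two-sided, adjusted over the 12 lists). The smallest p these draws can give is 0.0002. On simulated genes this test called a list with tripled density and 5.00% of 60 unchanged lists. The simulated regions were drawn independently at the same rate for all unchanged genes. Clustering of regions within genes and dependence on peak strength were left out, so these shares do not give the error rate in the real data. The lists were 5mC and 5hmC enzymes, germinal center B cell identity, plasma cell differentiation, B cell receptor signalling, CD40 and NF-kB signalling, antigen presentation, lymphoma suppressors and drivers, cell cycle, and markers of T cells, myeloid cells, erythroid and megakaryocyte cells, and neurons. Peak strength of a union region was the mean, over the libraries with a peak there, of the fold enrichment of its strongest peak.

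Genes were named by a rule set before the data were examined. It takes Tet1, Tet2 and Tet3; genes past the threshold of the gene-level fit, or else the 5 with the smallest p in each direction; the 10 genes with the most WT-higher regions; the 5 regions of highest score in each table; and up to 4 members of each list with the most WT-higher regions. Names starting with Gm and a digit or ending in Rik were left out of the gene-level part. Any other gene named was chosen after its values were seen. The value of 1 list member that the rule takes is not reported here.

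The alternatives were stricter peak thresholds (−log10 q or fold enrichment of at least 5), equal numbers of peaks, other overlap and merging rules, stricter differential regions, other scalings, pseudocounts, filters and test settings, the replicate number as a block, and each library left out in turn. Added after the data were seen were peaks thinned in proportion to the most frequent local background, lists without their richest gene, and counts expected at equal peak strength. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 did the remaining computing. Intervals for shares are 95% Wilson intervals and cover counting error only.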

Results

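TET2 is a dioxygenase that oxidizes 5-methylcytosine (5mC) to 5hmC, and the series asked how 5hmC in germinal center B cells differs with and without it. Germinal center B cells are the antigen-activated B cells that divide and mutate their antibody genes in lymphoid follicles. Genome-wide 5hmC was read as peaks of immunoprecipitated DNA in 2 WT and 2 KO libraries. The lists held 280416 peaks in KO replicate 2, 279548 in KO replicate 3, 270548 in WT replicate 2 and 300954 in WT replicate 3. They covered 137.0 Mb, 110.6 Mb, 124.8 Mb and 139.3 Mb in the same order, with median fold enrichments of 5.10, 4.38, 5.51 and 4.89.

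Tet2 itself (chromosome 3, 133463677 to 133545136) carried 5hmC peaks in all 4 libraries. Before scaling, peaks covered 3213 bases of its window in KO replicate 2, 2444 in KO replicate 3, 3191 in WT replicate 2 and 2810 in WT replicate 3. The limma log2 change, KO against WT, was 0.03 with a standard error of 0.14 and an adjusted p of 0.998. Peak coverage of the whole span does not read a deletion of part of the gene, so these values do not check the genotype labels. The authors' deposited table of WT-higher regions has 2 regions in Tet2, at 133480571 to 133480882 and 133484796 to 133485017, and both overlapped a peak in every library. The other family members had 1 WT-higher region in Tet3 and 0 in Tet1, with log2 changes of -0.20 (standard error 0.16, adjusted p = 0.992) and -0.12 (standard error 0.11, adjusted p = 0.992).

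The authors' deposited tables contain 24645 WT-higher regions and 50 KO-higher regions, so 99.8% of the listed regions were called lower in the knockout. Whether KO replicate 3 alone could give this imbalance stays open. The WT-higher regions had a median width of 258 bp, covered 7120 kb in all and lay in or within 2 kb of 5193 protein-coding genes, 28.4% of the 18310 genes with a union region. They were mostly not sites where the knockout lacked a peak: 18759 of them (76.1%) overlapped a peak in all 4 libraries, 894 overlapped a peak in both WT and no KO library, and 1223 overlapped no peak. A peak of WT replicate 2 overlapped 92.9% of the WT-higher regions, and one of WT replicate 3 90.0%, against 85.7% for KO replicate 2 and 76.9% for KO replicate 3. The WT mean was 10.1 percentage points above the KO mean, against 1.85 percentage points over all 356368 union regions. These regions were listed because WT exceeded KO, so this gap restates that choice, and the tables give no replicate values of their own.

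**Figure D1:**
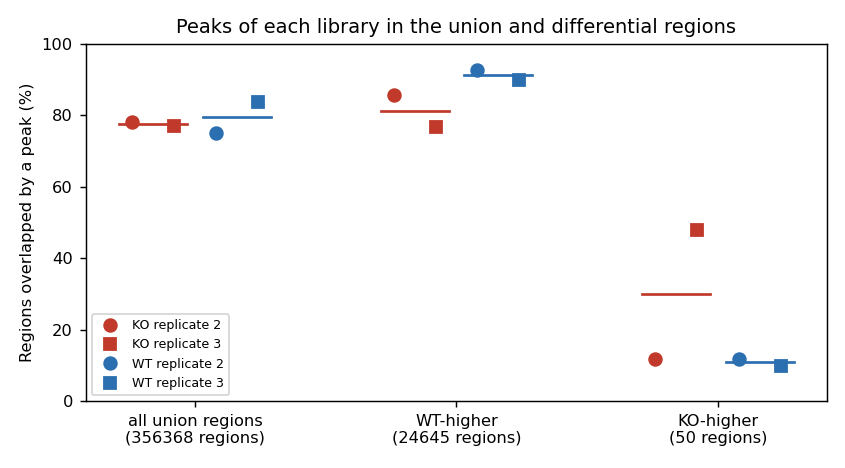
Share of regions (%, vertical axis) overlapped by a peak of each library, for all union regions and for the regions of the authors' deposited tables. Points are libraries and lines are means of 2 libraries; both WT libraries lie above both KO libraries for WT-higher regions (92.9% and 90.0% against 85.7% and 76.9%), and KO replicate 3 stands apart for KO-higher regions (48.0%).

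WT-higher regions were most numerous in Foxp1, Mtss1, Bach2 and Prkce. Foxp1, a forkhead transcription factor of B cell development (chromosome 6, 98925342 to 99522746), had 54, and 47 of its 180 union regions (26.1%, interval 20.2 to 33.0%) contained one. Over all genic union regions that share was 7.26%. Bcl11a, a zinc finger factor required for B cell development (chromosome 11, 24076564 to 24173558), had 25, with 20 of 49 union regions (40.8%, interval 28.2 to 54.8%). Mtss1, an actin-binding protein gene, had 36 and a share of 38.0%; Rftn1, which encodes a lipid raft protein, had 25 and 31.6%. Bach2, a repressor that restrains plasma cell differentiation, had 33 (23.6%), Ebf1, an early B cell factor, had 26 (22.9%), and Prkce, a protein kinase C gene, had 33 (21.7%). The very long genes Rbfox1, Cdh13 and Dlg2 had 30, 28 and 28 regions but lower shares of 11.6%, 13.3% and 10.7%. At a score of at least 5 in the authors' deposited table, Foxp1 kept 37 regions, Mtss1 25, Bach2, Prkce and Rbfox1 19 each, Ebf1 15, Bcl11a 14, Cdh13 and Dlg2 12 each and Rftn1 9.

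**Figure D2:**
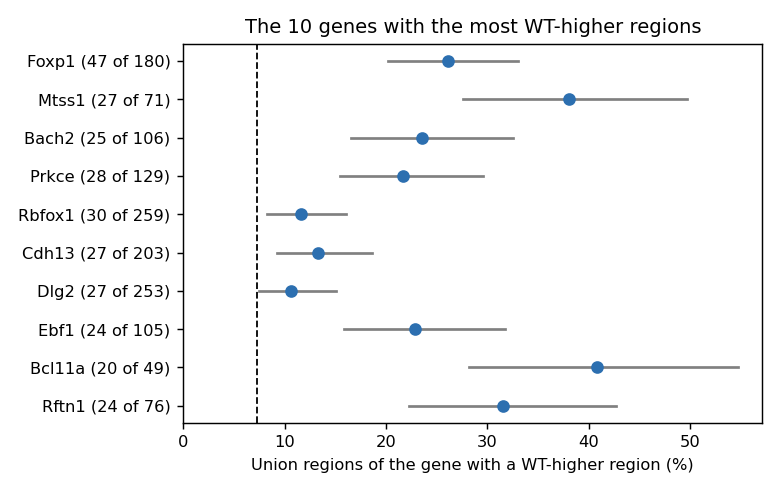
Percentage of each gene's union regions that contain a WT-higher region (horizontal axis) for the 10 genes with the most WT-higher regions, with counts beside the names. Bars are 95% Wilson intervals and the dashed line is the share over all genic union regions (7.26%); Bcl11a reached 40.8% and Mtss1 38.0%.

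The 5 WT-higher regions with the highest score in the authors' deposited table lay in Sidt2 (chromosome 9, 45941175 to 45941594, score 22.6), Grm7 (chromosome 6, 111376993 to 111377371, 18.4), outside protein-coding genes on chromosome Y (3865304 to 3865570, 17.5), Ctse (chromosome 1, 131641456 to 131641978, 17) and Foxp4 (chromosome 17, 47900185 to 47900501, 16.7). The Ctse region overlapped a peak in both WT libraries and in neither KO library. That of Sidt2 lacked a peak in KO replicate 3, and that of Foxp4 had none in any library.

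Among the fixed gene lists, WT-higher regions were dense in germinal center B cell identity genes and in lymphoma suppressors and drivers. Random lists came from all protein-coding genes with peak coverage and were not matched on activity in these cells. The identity list had 3.73 regions per 10 kb of union peak coverage, 2.12 times the median of matched random lists (adjusted p = 0.0012), with 166 regions in 23 of its 30 genes. Besides Bach2 and Ebf1, the leading members were Foxo1, which supports the dark zone program, with 19 regions and Pax5, the B lineage commitment factor, with 17. Lymphoma genes had 79 regions in 18 of 29 genes, a ratio of 2.13 (adjusted p = 0.0012); Hvcn1 had 12, Itpkb, a kinase gene, 10 and Bcl2, the antiapoptotic gene, 8. These lists share 5 genes, Foxo1 among them. B cell receptor signalling genes had 133 regions in 20 of 26 genes, a density of 2.87 against 1.92 in random lists (adjusted p = 0.0392), led by Nfatc1 with 18, Plcg2 and Prkcb with 15 each and Vav2 with 12. This last call ended with random lists matched on gene length (ratio 1.76, adjusted p = 0.0728), where the random lists spread more widely, with regions of score at least 5 (1.42, 0.311) and without Nfatc1 (1.37, 0.214), where the ratio was lower. At equal peak strength the list passed with a ratio of 2.07 to random lists (adjusted p = 0.0032).

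No other list passed in the main test. At equal peak strength, CD40 and NF-kB signalling (2.17, adjusted p = 0.0090), antigen presentation (2.18, 0.0355) and cell cycle genes (2.43, 0.0472) passed too. In the main test, the ratio was 1.92 for 5mC and 5hmC enzymes (adjusted p = 0.155), where Zbtb38, a methyl-CpG-binding protein gene, held 10 of 15 regions and Dnmt3a had 1. It was 1.55 for CD40 and NF-kB signalling (0.194), with 4 regions in Nfkb1, 3 in Cd40 and 2 each in Bcl2l1 and Birc3, and 1.52 for antigen presentation (0.265), with 5 in Cd74, 4 in Ciita and 2 each in B2m and H2-Aa. Cell cycle genes had 1.46 (0.393), with 10 regions in Ccnd3, 8 in Cdk6, 5 in E2f2 and 1 in E2f3, and plasma cell genes 1.3 (0.446), with 8 in Zbtb20 and 3 each in Atf6, Creb3l2 and Slamf7. Of the lists for other cell types, myeloid markers had 1.42 (0.446; Adgre1 4, Itgax 2, Mertk 2, Csf1r 1), neuronal genes 1.03 (0.858; Nrxn3 21 and Csmd1 19 after Rbfox1 and Dlg2), T cell markers 0.869 (0.707; Skap1 4, Themis 2, Cd247 1) and erythroid and megakaryocyte markers 0.343 (0.446; 1 region, in Zfpm1). The number of members with at least 1 region passed for 0 of the 12 lists. With matching on gene length in place of peak coverage, 6 passed with adjusted p of 0.038 or less: germinal center B cell identity (23 genes; 10 in random lists matched on length, 20 in those matched on coverage), B cell receptor signalling (20; 11 and 18), CD40 and NF-kB signalling (15; 7 and 10), antigen presentation (12; 3 and 8), lymphoma genes (18; 9 and 14) and plasma cell genes (10; 5 and 7). Length matching leaves the peak coverage of these lists uncorrected.

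**Figure D3:**
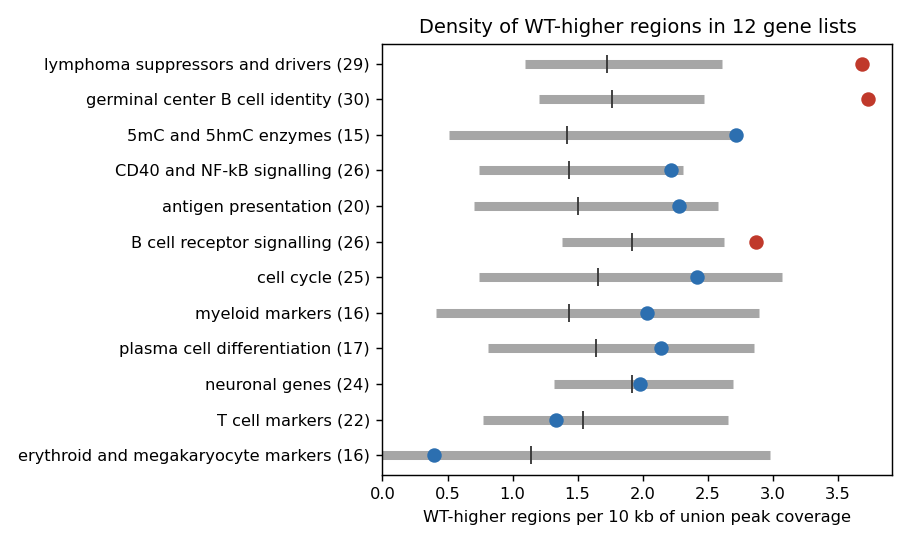
WT-higher regions per 10 kb of union peak coverage (horizontal axis) in the 12 gene lists, with the number of genes in parentheses. Points are the lists, red where the adjusted p was under 0.05; gray bars span the central 95% of 10000 matched random lists and ticks mark their medians. Germinal center B cell identity (3.73) and lymphoma genes (3.69) lie beyond the bars.

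WT-higher regions favored gene interiors. Midpoints inside genes made up 42.5% of WT-higher and 35.8% of union regions (log2 ratio 0.25, interval 0.22 to 0.28), and midpoints outside genes 52.1% and 58.6% (log2 ratio -0.17, interval -0.20 to -0.14). Shares within 2 kb of a gene end were 5.41% and 5.65% (log2 ratio -0.06, interval -0.14 to 0.02), a difference within its interval. Stronger peaks contained a WT-higher region more often: on autosomes the share was 2.59% in the weakest of 20 strength bins and 28.4% in the strongest. It was also 8.90% of union regions called in all 4 libraries and 1.92% of those called in 1.

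The X chromosome carried few WT-higher regions. They occurred in 94 of 12587 union regions on X (0.747%, interval 0.611 to 0.913%) and in 6.71% of autosomal union regions, where chromosomes 7 and 10 had the lowest and highest shares, 5.86% and 7.64%. At the autosomal rate for equal peak strength, 670 regions would be on X. Chromosome Y had 21 of 2684 (0.782%, interval 0.512 to 1.19%). In the authors' deposited table of KO-higher regions, by contrast, 9 of 50 were on X. The labels do not give the sex of the animals.

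**Figure D4:**
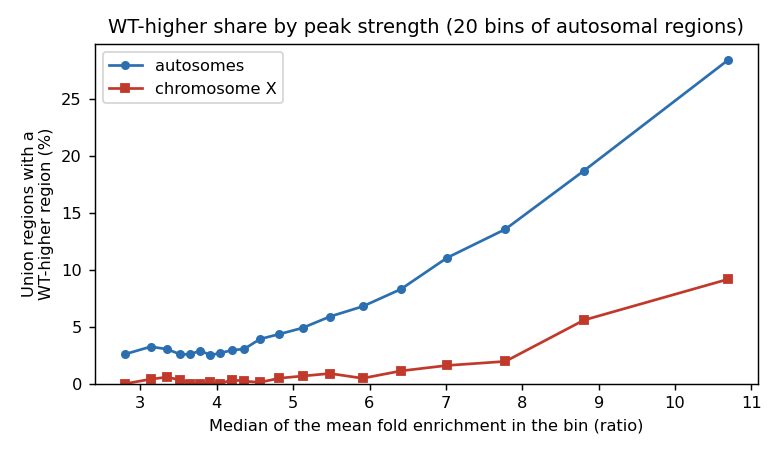
Percentage of union regions with a WT-higher region (vertical axis) against the median fold enrichment of 20 strength bins (horizontal axis, ratio), for autosomes and chromosome X. In the strongest bin the share was 28.4% on autosomes and 9.17% on X.

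KO-higher regions were few, and their median score in the authors' deposited table was 4.83, beside 4.77 for WT-higher regions. Of the 50, 26 overlapped no peak of any library and 17 a peak of KO replicate 3 alone, so that 48.0% had a peak in KO replicate 3, 12% in KO replicate 2, 12% in WT replicate 2 and 10% in WT replicate 3 (KO mean 30%, WT mean 11%), in regions listed because KO exceeded WT. The 5 of highest score in the authors' deposited table lay in Wdfy3 (chromosome 5, 102053882 to 102054088, score 12.3), Catip (chromosome 1, 74365238 to 74365445, 9.03), Trim55 (chromosome 3, 19667657 to 19667860, 8.71), outside protein-coding genes on X (85430046 to 85430291, 7.64) and Arsg (chromosome 11, 109553957 to 109554156, 6.61). Vav1, a guanine nucleotide exchange factor gene of blood cells, held 3 of the 50 in its span and 1 in the 2 kb before it. These lay between 57277508 and 57291500 on chromosome 17, and Vav1 was singled out after its values were seen. Its window also held 2 WT-higher regions. Each of its KO-higher regions overlapped a peak in every library, except the one at 57279321 to 57280163, which had none in WT replicate 3.

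**Figure D5:**
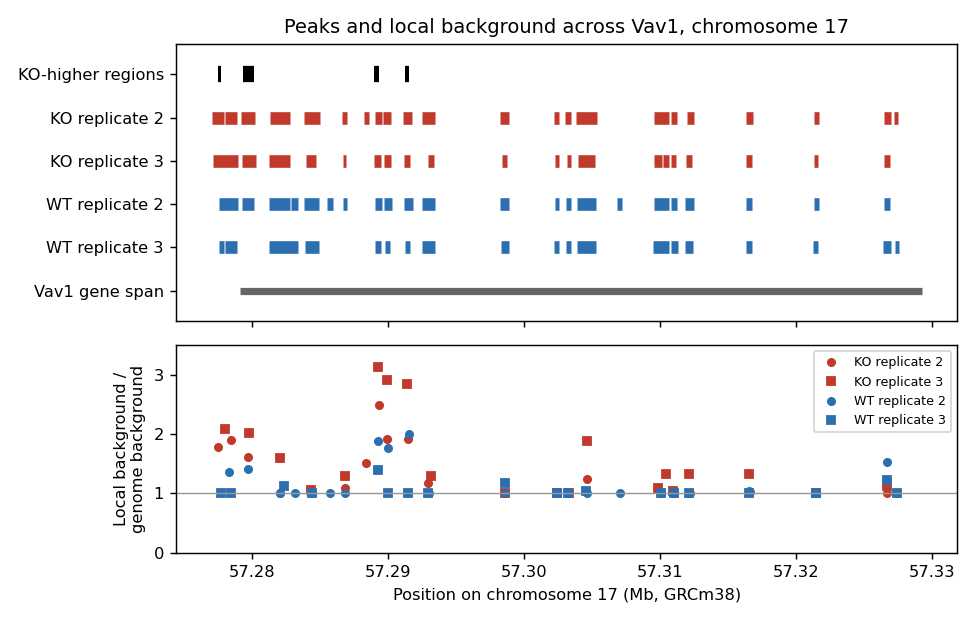
Peaks of each library, KO-higher regions and the Vav1 span on chromosome 17 (horizontal axis, Mb), above the local background of each peak relative to the genome background of its library (vertical axis, ratio). The 4 KO-higher regions lie in the first part of the window (span plus 2 kb on both sides), 1 of them outside the span, where the median ratio was 1.70 in KO replicate 2, 2.05 in KO replicate 3, 1.18 in WT replicate 2 and 1 in WT replicate 3.

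Presence or absence of peaks, taken from the individual lists, separated the genotypes little. Of 356368 union regions, 213431 (59.9%) had a peak in every library, 6852 had one in both WT and no KO library, and 4695 in both KO and no WT library. The total of 11547 was below those of the other splits, 14725 when KO replicate 2 and WT replicate 2 were set against the rest and 13127 when KO replicate 2 and WT replicate 3 were. With peaks of at least 5-fold enrichment the counts were 7757 and 743, and the split of KO replicate 2 and WT replicate 2 gave 9917 and 928; that of KO replicate 2 and WT replicate 3 gave 4294 and 1423, a total of 5717 and so below the 8500 of the genotype split. The excess of WT-only regions turned around without KO replicate 3 (ratio 0.904 in place of 1.46) and without WT replicate 3 (0.966), and it rose to 2.97 without WT replicate 2. It was 1.01 without KO replicate 2 and 1.01 with equal numbers of peaks (5389 WT-only and 5347 KO-only regions).

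Peak number and overlap did not follow genotype. The mean difference in peak number, KO minus WT, was -5769 (279982 against 285751, exact permutation p = 1), and 9434 without WT replicate 3. Jaccard indices averaged 0.670 within genotypes and 0.685 between them; the lowest pair was KO replicate 2 with KO replicate 3 (0.625) and the highest KO replicate 2 with WT replicate 2 (0.729).

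Summed over whole genes, 5hmC peak coverage did not separate WT from KO for any single gene. The measure counts bases under called peaks and not peak height, and scaling to equal totals removes a change shared by all genes. A difference in height at peaks called in every library, where most WT-higher regions lay, can therefore be missed. In limma, 0 of 14001 genes were higher and 0 lower in KO at an adjusted p under 0.05; 568 had an unadjusted p under 0.05, where 700.05 would arise by chance, and the smallest adjusted p was 0.992. The unadjusted count was 875 without KO replicate 2 (693.75 by chance) and 377 without KO replicate 3 (712.95 by chance). The genes with the smallest p among the lower values were Klc1 (kinesin light chain; log2 change -0.60, standard error 0.09), Tram2 (-0.60, 0.09), Fbxl20 (-1.45, 0.23), Msl2 (-1.12, 0.18) and Gadd45a, a DNA damage and demethylation factor (-1.23, 0.21). On the higher side they were Dnhd1 (0.62, 0.12), Plac9a (0.93, 0.18), Phf20l1 (0.84, 0.16), Larp1b (0.49, 0.10) and Btg1, an antiproliferative gene mutated in lymphoma (0.84, 0.18). None of these 10 passed (adjusted p = 0.992 for each). Scaled Gadd45a coverage was 388 and 362 bases in KO and 1226 and 1077 in WT; for Btg1 it was 1508 and 1855 in KO and 904 and 787 in WT. Among peaks of at least 5-fold enrichment the sign of Larp1b and Tram2 turned (-0.22 and 0.17), Klc1 shrank to -0.08 and Dnhd1 to 0.13, Btg1 was 1.45, and Plac9a, Phf20l1, Fbxl20, Msl2 and Gadd45a had too little coverage to be tested. With equal numbers of peaks, Btg1 shrank to 0.31, Klc1 to -0.36, Tram2 to -0.37, Fbxl20 to -0.97, Msl2 to -0.63 and Gadd45a to -0.85. Dnhd1 (0.60), Plac9a (0.91), Phf20l1 (0.83) and Larp1b (0.47) changed little there.

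Camera ranked 4 of the 12 lists apart from other genes, none of them when the inter-gene correlation was estimated (adjusted p = 0.778 for each with an estimated correlation). Coverage was lower in KO for 10 of 12 measured genes of the 5mC and 5hmC enzyme list (median log2 change -0.14, camera adjusted p = 0.0124), 14 of 18 antigen presentation genes (-0.14, 0.0172) and 17 of 24 CD40 and NF-kB genes (-0.16, 0.0270). It was higher for 20 of 22 neuronal genes (0.09, 0.0111). The enzyme list also holds genes for binding proteins and cofactors. Zbtb38, Uhrf1 and Hells had its smallest unadjusted limma p (0.0027, 0.0082 and 0.042). For Tet1, Tet2, Tet3, Dnmt1 and Dnmt3a the unadjusted limma p ranged from 0.258 to 0.886. Many antigen presentation genes are close neighbors on chromosome 17. Windows of Psmb9, Tap1, Psmb8 and Tap2 overlap and can count the same peaks, so these members are not independent. Adjusted over the list alone, 2 genes passed, both in the enzyme list: Zbtb38 (-0.60, standard error 0.11, adjusted p = 0.0325) and Uhrf1, the maintenance methylation cofactor (-1.20, standard error 0.28, 0.0490). Neither passed with any 1 library left out; over all genes tested, 0 members of any list passed. The identity list had 20 of 30 genes lower (-0.12, 0.120), with an adjusted p of 0.0362 without KO replicate 2 and 1.8e-07 without WT replicate 3, but 21 of 30 genes were higher without WT replicate 2 (0.07, 0.206). The remaining 7 lists had camera adjusted p of at least 0.273. Without KO replicate 3 or without WT replicate 2 no list passed, and 7 did without WT replicate 3. Scaling set the median log2 change over all genes at 0.02, against -0.10 without scaling, where 17 of 22 neuronal genes were lower and that list did not pass (adjusted p = 0.193), nor did CD40 and NF-kB signalling (0.158).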

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

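Peaks thinned to an equal most frequent local background, lists without their richest gene, expectations at equal peak strength and the checks of score on chromosome X and on the named genes were chosen after seeing the data. Thinning left unequal peak numbers (270344 to 296998) and changed no call or direction among the results it was run on. It recomputed only the p at each summit and left the widths of the kept peaks as deposited. Few peaks were lost: 277793 of 280416 remained in KO replicate 2 and 296998 of 300954 in WT replicate 3. It could therefore change little, and an effect of depth is not excluded. The difference in peak number between KO and WT ranged from -20972 to 9434 with 1 library left out, turning without WT replicate 3. WT-only regions then ranged from 13987 to 29195 and KO-only regions from 9822 to 23328, since fewer libraries must agree. Their ratio ranged from 0.904 to 2.97. At 5-fold enrichment there were 743 KO-only regions and a ratio of 10.4. KO replicate 3 had 100175 peaks there, against 144225 to 159906 in the other libraries. The side holding KO replicate 3 had fewer regions in every split, also where genotypes were mixed (928 against 9917, and 1423 against 4294). The excess at this threshold therefore does not speak for genotype. The gene-end log2 ratio was 0.0403 with 1 kb flanks and passed at -0.12 with any overlap of 1 bp; the cause was not tested. Without a filter, limma called 34 genes (15 higher, 19 lower) in place of 0, and every other setting 0; the cause was not tested. Tet2 was -0.089 unscaled and -0.11 to 0.17 with 1 library left out; the share of WT-higher regions on X was 1.58% among regions of at least 500 bp and 0.330% at a score of at least 5, against 0.434%; at 5-fold enrichment Larp1b was -0.22 and Tram2 0.17. Of 210 alternative values for the 13 genes named from the gene-level fit, 205 kept their sign, whatever their size, and 5 turned. Camera called 0 lists with an estimated correlation, 2 without scaling and 0 to 7 with 1 library left out, where the adjusted p for antigen presentation ranged from 1.6e-05 to 0.956 and its direction turned without WT replicate 2, as did that of the identity list. A lone library of a genotype was assumed to vary like the other group. With the replicate block, 0 genes and 6 lists passed (4 without), the identity list among them (camera adjusted p = 0.0074). An unadjusted p under 0.05 was reached by 828 genes with the block and 568 without. Deviations of same-numbered libraries correlated at 0.09. A single correlation from 2 libraries per genotype cannot decide whether the numbers pair the libraries, and the labels do not say. The density test called 6 lists at equal peak strength in place of 3, and the B cell receptor ratio no longer passed at 1.76 (matched on gene length), 1.42 (score of at least 5) and 1.37 (without Nfatc1). By members with a region, 6 lists passed when matched on gene length and 2 at a score of at least 5, in place of 0. The overlap of peak sets, the WT-minus-KO shares of peaks in differential regions, the share of listed differences that are WT-higher and the shares inside and outside genes kept their direction in every alternative run, of which only the last were set against an interval that could have lost a call. Gene windows around transcription start sites and CpG content were not run, for lack of strand and sequence. Reads per library are unknown, so no error from counting was set on peak coverage.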

Other observations

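The patterns below were picked after the data were seen; the tests of Vav1, of ranks, of peak strength and of single genes were chosen after that, whereas matching on gene length was set beforehand but its reading as a test of this pattern came after its result.

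Given the strength of their peaks, more lists were rich in WT-higher regions than by density alone. Observed over expected regions were 4.33 for germinal center B cell identity genes, 3.57 for lymphoma genes, 2.90 for cell cycle genes, 2.85 for B cell receptor signalling, 2.41 for antigen presentation and 2.33 for CD40 and NF-kB signalling, each with an adjusted p of 0.0472 or less. Of the 23 regions observed for cell cycle genes, 10 lay in Ccnd3 and 8 in Cdk6, and equal strength was not run without them. For T cell markers the ratio was 0.966 and for neuronal genes 1.33, both inside the range of random lists.

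Sex chromosomes differed between libraries in ways that did not follow genotype. Among regions called in all 4 libraries, the median rank of fold enrichment on X was 43.9 in KO replicate 2, 42.7 in KO replicate 3, 43.4 in WT replicate 2 and 36.5 in WT replicate 3 (percentile within the library). On Y it was 60.9, 28.6, 57.1 and 58.0. Regions on X made up 0.434% of all WT-higher regions and 1.58% of those of at least 500 bp. Every library had peaks on Y: 1733 in KO replicate 2, 1109 in KO replicate 3, 1642 in WT replicate 2 and 2378 in WT replicate 3. The sex of the animals is not given in the labels, so the shares on X and Y have no known reference.

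WT-higher regions were dense in germinal center B cell identity genes, and 3 technical accounts were tested. Stronger peaks in these genes do not account for it: the ratio at equal strength was 4.33, above the random lists' upper limit of 1.90, and the median strength in these genes was 3.86 against 4.33 over all genic regions. Gene length does not account for it either, with a density ratio of 2.41 against lists matched on length (adjusted p = 0.0024), nor does a single gene, with 2.04 without Bach2 (adjusted p = 0.0024). In whole-gene peak coverage, the direction of this list depended on single libraries. Of its 30 genes, 15 were lower in KO without KO replicate 3 and 23 without KO replicate 2. Without WT replicate 2, 9 were lower, and without WT replicate 3, 25. Whether 1 library, such as KO replicate 3, gave the density of WT-higher regions was not tested. A lower share of germinal center B cells in the KO samples was not tested, nor was activity of the genes in these cells. The authors' choice of libraries and thresholds is not stated in the sources used here, beyond unexplained tags in the names of the deposited tables. These stay open.

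The imbalance of 24645 WT-higher against 50 KO-higher regions could come from KO replicate 3 alone, the library with the lowest median fold enrichment. Among regions called in all 4 libraries, the median rank of WT-higher regions was 78.0 in KO replicate 2, below WT replicate 2 (80.5) and just below WT replicate 3 (78.5), a gap to the latter smaller than that between the WT libraries. A scaling difference would leave ranks alike; the rank was 70.8 in KO replicate 3, well below both, and 78.0 in KO replicate 2, which was not. The WT-higher regions had a median fold enrichment of 7.97 in KO replicate 2 and 5.81 in KO replicate 3. In WT replicates 2 and 3 it was 9.01 and 7.80. Relative to other shared regions the ratios were 1.41 and 1.21 in KO, and 1.48 and 1.38 in WT. On this measure only KO replicate 3 was low, as an effect of KO replicate 3 alone would give. These accounts cannot be told apart from a loss of 5hmC with TET2. Both KO ranks were below both WT ranks in 26.9% of WT-higher and 13.9% of other shared regions, where chance gives 16.7%, but the WT-higher regions were chosen for this difference.

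The 4 KO-higher regions in the first part of the Vav1 window, 1 of them in the 2 kb before the span, are more than a general gain of peaks in KO would place there (0.00323 expected; the chance that any gene holds as many, summed over genes because Vav1 was picked for its count, was 1.02e-06 in a binomial model that treats neighboring regions as independent). Extra copies of this DNA in the KO libraries are a candidate explanation: the local background in this part was 1.70 times that in the rest of Vav1 in KO replicate 2 and 1.85 times in KO replicate 3, against 1.18 and 1 in WT. Bootstrap intervals of KO replicate 2 (1.09 to 1.92) and KO replicate 3 (1.15 to 2.77) overlap that of WT replicate 2 (0.997 to 1.77), and that of KO replicate 2 also overlaps that of WT replicate 3, so the KO excess is not cleanly separated. Regulatory DNA of Vav1 is often used in transgenes that express Cre in blood cells, but the labels name no transgene. If the background was taken from the immunoprecipitated DNA, a true gain of 5hmC would raise it too, so this stays open.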
